A study of Aspergillus nidulans with 6 samples.

How the data were processed

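The series holds 6 RNA-seq libraries of the filamentous fungus Aspergillus nidulans, 3 from a strain with an intact mcrA gene (LO1362, here WT) and 3 from a strain in which mcrA had been deleted (LO8158, here mcrA-deleted). Per the labels' protocols, spores were grown in liquid glucose minimal medium for 1 day at 37 °C (1000000 spores in 150 ml), with uridine, uracil, pyridoxine and riboflavin added. Mycelium was frozen, RNA was extracted, and strand-specific libraries were made from polyadenylated RNA and sequenced on a MiSeq. The labels call the libraries replicates and do not say that they came from separate cultures. The p-values therefore measure the spread between these libraries, which may be partly technical. Each genotype is 1 strain, so any other difference between the strains cannot be told apart from the deletion.

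The deposited files hold 1 raw read count per feature and library, with no normalization, and the same 10983 features stand in all 6 files. Of these, 10740 carry an AN gene number and the rest are mainly tRNA, mitochondrial and other small features. Per the submitters' processing notes, CASAVA and HISAT (version 1) were used. The counting tool, its use of strand, its treatment of reads with several hits and the annotation release are not given in the sources used here. Per the file headers, each feature has a chromosome, start, end and strand; coordinates below are those of the files, whose chromosomes are named for A. nidulans FGSC A4. In the deposited order, 949 pairs of adjacent gene features overlapped, so reads in the shared part can belong to either gene. Among the 102 tested genes chosen as described below, 12 overlapped another feature, and their levels are uncertain to that extent: wA, ivoB, agsA, stuA, velC, AN12400, AN6443, AN1242, AN2319, AN2557, AN3231 and AN8439. Untested features given by their counts were not part of this check, and aflR among them overlapped AN7821. No column of per-sample values was left unmapped (0 columns).

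Total counts per library were 4739323, 6051839 and 4797268 in WT replicates 1 to 3, and 3374534, 4926520 and 4419465 in mcrA-deleted replicates 1 to 3. A count of 0 summed over a group of 3 libraries allows up to 3 counts, which is 0.203 counts per 1000000 counts (CPM) in WT and 0.222 CPM in the mcrA-deleted group. Folds against a group with 0 counts in all libraries are given as lower bounds against that floor, summed over the group. For groups with 1 to 3 counts the ratio of pooled counts is given with its exact binomial 95% interval. Floors and intervals cover counting error only, since reads were not marked with molecular identifiers. Pairs of replicate libraries differed by 9.97 to 54.1 times the chi-square per degree of freedom of sampling noise, so none was treated as a repeat of another.

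The comparison of the genotypes used edgeR 4.0.16 in R 4.3.3 on the counts as deposited: trimmed-mean (TMM) scaling, filterByExpr with its default settings (minimum count 10), and the quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided, with genotype as the only term. A gene was called at an adjusted p under 0.05. The filter kept 7852 features and left out 3131. TMM factors ranged from 0.8612 to 1.108. Log2 fold changes are mcrA-deleted over WT, with standard errors taken from the fold change and its F statistic. CPM values use the TMM-scaled library sizes and are given as mean ± SD over 3 libraries.

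The test, the alternatives and 30 gene lists were chosen before the data were examined. The lists were written from background knowledge of A. nidulans loci and cover 16 named metabolite clusters, all of these together, backbone enzymes of secondary metabolism, regulators, development, primary metabolism, iron, stress, cell wall and the marker genes of common laboratory strains. Lists with at least 3 tested members, 20 in all, were tested with camera in limma 3.58.1 (preset correlation 0.01) with adjustment over the lists. An estimated correlation and fry were the alternatives. Lists share members: 24 of 66 listed backbone enzymes, 6 of 17 regulators, 4 of 16 asexual and 4 of 7 sexual development genes stand in other lists too. Results of lists that share members are not separate. Symbols are those written in the lists. The RefSeq table of the assembly ASM1142v1 was used for names only; 10032 features matched it and 779 had a symbol there. The genes named are mcrA, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group averaged at least 20 counts, up to 4 called members of each list (or 2 members of highest level where none passed), and 3 genes of each of the 5 longest runs of adjacent called genes. Ties among runs of 4 genes were broken, after the data were seen, by the largest absolute log2 fold change in the run. That rule gave 86 genes, and 16 others were chosen after their values were seen. These are named as such where they appear, except agsB, velB, gpdA and yA, which were also chosen after their values were seen. Untested features given by their counts, such as aflR and stcA, lie outside both numbers.

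Adjacent genes called in the same direction were counted along the chromosomes and set against 10000 random placements of the calls on the tested genes. Alternatives were DESeq2's size factors, library size alone, the DESeq2 1.42.0 Wald test, no count filter, a mean count of at least 50, the replicate number as a block, each library left out in turn, and stricter thresholds. Added after seeing the data were fits without WT replicate 3 and mcrA-deleted replicate 1 together, without mitochondrial features, and with every library thinned to 3374534 counts. Tested on simulated data with 200 of 7852 genes changed, the edgeR fit recovered 5.97% of the 1.5-fold changes, 39.7% of the 2-fold changes and 85.7% of the 4-fold changes, with 6 false calls among 95. With more genes called, the adjustment asks less of each p-value. The data had 2343 calls, so these shares do not measure recovery there.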

Results

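RNA-seq counts were compared between 3 WT and 3 mcrA-deleted libraries of A. nidulans grown for 1 day in glucose minimal medium. The gene mcrA encodes a protein described as a negative regulator of secondary metabolism in this fungus. The comparison asks which transcripts differ in level when mcrA is deleted. Depth lay between 3374534 counts (mcrA-deleted replicate 1) and 6051839 counts (WT replicate 2), and the 7852 tested features held nearly all counts.

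The mcrA transcript itself was measured first. No label pairs the gene with a locus number; AN8694 (chromosome III, 3100552 to 3102696, plus strand) is its locus from background knowledge. Its feature had 674, 903 and 655 counts in WT replicates 1 to 3 and 280, 422 and 273 counts in mcrA-deleted replicates 1 to 3. The level was 152 ± 6.21 CPM in WT and 72.7 ± 14.6 CPM in the mcrA-deleted libraries (SD, n = 3 each), 48.0% of WT. The log2 fold change was -1.06 (SE 0.168; adjusted p = 0.00468 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). An exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 libraries allow. All 3 mcrA-deleted libraries lay below all 3 WT libraries, so the feature separated the labelled genotypes, but it was not empty in any mcrA-deleted library. The counts do not place reads within the feature, and the deleted part of the gene is not given in the sources used here.

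The transcriptomes separated by genotype. The first principal component held 77.0% of the variance of log2 CPM and placed the WT libraries between -64.4 and -33.7 and the mcrA-deleted libraries between 40.8 and 62.5. WT replicate 3 stood apart from the other WT libraries on the second component (-38.0, 10.5% of the variance). Mitochondrial features took 1.06% of counts in mcrA-deleted replicate 1 and 0.0593% to 0.159% in the other 5 libraries.

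**Figure D1:**
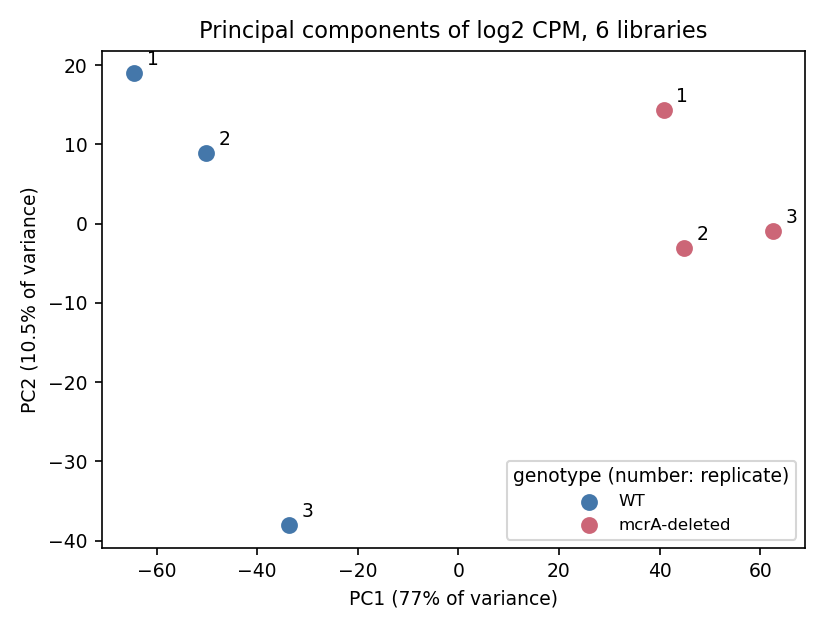
First and second principal components of log2 CPM for the 6 libraries (points; the number beside each point is the replicate), with the percentage of variance on each axis. WT libraries lie between -64.4 and -33.7 on the first component and mcrA-deleted libraries between 40.8 and 62.5.

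The mcrA-deleted strain differed broadly from WT in transcript levels. Of 7852 tested genes, 1265 were higher and 1078 lower in the mcrA-deleted libraries (edgeR's quasi-likelihood test, adjusted p under 0.05), together 29.8%. The larger changes were mostly rises: 813 of the genes called higher and 397 of those called lower had an absolute log2 fold change of at least 1, and 449 and 100 had at least 2. Of the 2343 called genes, 2335 had groups that did not overlap; over all tested genes this share was 48.9%, where chance gives 10%. With library size alone in place of TMM, 1660 genes were higher and 639 lower, so that 72.2% of the calls were rises against 54.0% with TMM. That scaling moved the median log2 fold change of all genes by 0.171, and the directions given here are relative to TMM. Genes higher and lower numbered 895 and 686 without WT replicate 1, 758 and 620 without WT replicate 2, 844 and 618 without mcrA-deleted replicate 2, and 865 and 651 without mcrA-deleted replicate 3.

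Among the 10 largest rises, AN1242, a nonribosomal peptide synthetase gene (chromosome VIII, 1072779 to 1092126), went from 1.59 ± 1.57 CPM in WT to 775 ± 334 CPM in the mcrA-deleted libraries (log2 fold change 9.02, SE 0.651; adjusted p = 0.000447, edgeR's quasi-likelihood test). AN3983 (chromosome II, 2429832 to 2431150) had 0, 0 and 2 counts in WT against 203, 350 and 3645 in the mcrA-deleted libraries, a pooled ratio of 2290 (95% interval 635 to 18900). AN8433 (chromosome V, 468993 to 471591) had a pooled ratio of 1470 (503 to 7130) and AN8370, also on chromosome V, one of 767 (137 to 30300). The other 6 had 0 counts in all WT libraries. They were at least 122.7-fold (AN5664), 111.4-fold (AN8439), 98.5-fold (AN8775), 64.5-fold (AN2557), 54.9-fold (AN12400) and 54.5-fold (AN5244) higher in the mcrA-deleted libraries. Rises and falls were ranked by fitted log2 fold change. For these 6 genes the fitted values lay above the bounds, so their places among the largest rises are uncertain. For AN3983, AN8433, AN8439, AN8775, AN2557, AN12400 and AN5244 the count in mcrA-deleted replicate 3 was well above those in replicates 1 and 2. Without that library the pooled ratios of AN3983 and AN8433 were 473 (130 to 3920) and 783 (267 to 3800), and the bounds of AN8439, AN8775, AN2557, AN12400 and AN5244 were 39.7, 32.3, 25.65, 26.4 and 13.8-fold. The WT counts of AN3983 and AN8370 lay in replicate 3 alone, and without it these genes were at least 1031-fold and 179.8-fold higher. Those of AN8433 lay in replicate 2 alone, and without it this gene was at least 836.2-fold higher. Leaving out WT replicate 2, the deepest library, also gave ratios of 1350 (375 to 11200) for AN3983 and 453 (81.0 to 17900) for AN8370. It left bounds of 72.4-fold for AN5664 and, for the genes from AN8439 to AN5244 in the order just given, 65.8, 58.1, 38.05, 32.4 and 32.2-fold. Without WT replicate 3, which held 14 of its 21 WT counts, AN1242 rose by 10.14. The call of AN8775 was lost without WT replicate 2 (adjusted p = 0.0615; 8.47e-05 to 0.0615 over all refits), that of AN8439 without WT replicate 2 (0.0585) or mcrA-deleted replicate 2 (0.0507; 7.56e-05 to 0.0585 over all refits), and that of AN5244 without WT replicate 1 (0.056) or 2 (0.0764; 0.000695 to 0.0764 over all refits), all in the quasi-likelihood test except the lowest values, which are DESeq2's.

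Among the 10 largest falls, AN2392 (chromosome VII, 3782043 to 3783653) had 53, 52 and 40 counts in WT and 0 in all mcrA-deleted libraries, at least 44.8-fold lower. AN3259 on chromosome VI and AN8134 on chromosome II kept 1 and 2 counts over the mcrA-deleted group, with pooled ratios of WT to mcrA-deleted of 219 (38.9 to 8670) and 82.3 (22.5 to 685). AN1567 kept 2 counts, with a ratio of 49.0 (13.2 to 409). AN5540 (chromosome V, 2466983 to 2469028) had the highest WT level of the 10, 232 ± 63.5 CPM, and stood at 5.59 CPM in the mcrA-deleted libraries. AN8137, AN9388, AN2319 and AN7832 had log2 fold changes of -5.26, -4.99, -4.84 and -4.75, and AN2649 went from 64.7 ± 13.9 to 2.21 ± 2.34 CPM. Without mcrA-deleted replicate 1 the values of AN7832 and AN2649 were -5.87 and -6.14, and AN3259 and AN1567, whose remaining counts lay there, were at least 54.2-fold and 22.2-fold lower. Without mcrA-deleted replicate 2 the ratios of AN3259, AN8134 and AN1567 were 136 (24.1 to 5380), 51.1 (13.9 to 425) and 30.4 (8.2 to 254), and AN2392 was at least 27.8-fold lower. Without mcrA-deleted replicate 3 those of AN3259 and AN1567 were 140.0 (24.8 to 5540) and 31.3 (8.44 to 261), and AN2392 was at least 28.6-fold lower. AN1567 had a ratio of 27.1 (6.97 to 233) without WT replicate 2. The calls of these 10 genes held in each fit that left out 1 library.

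**Figure D2:**
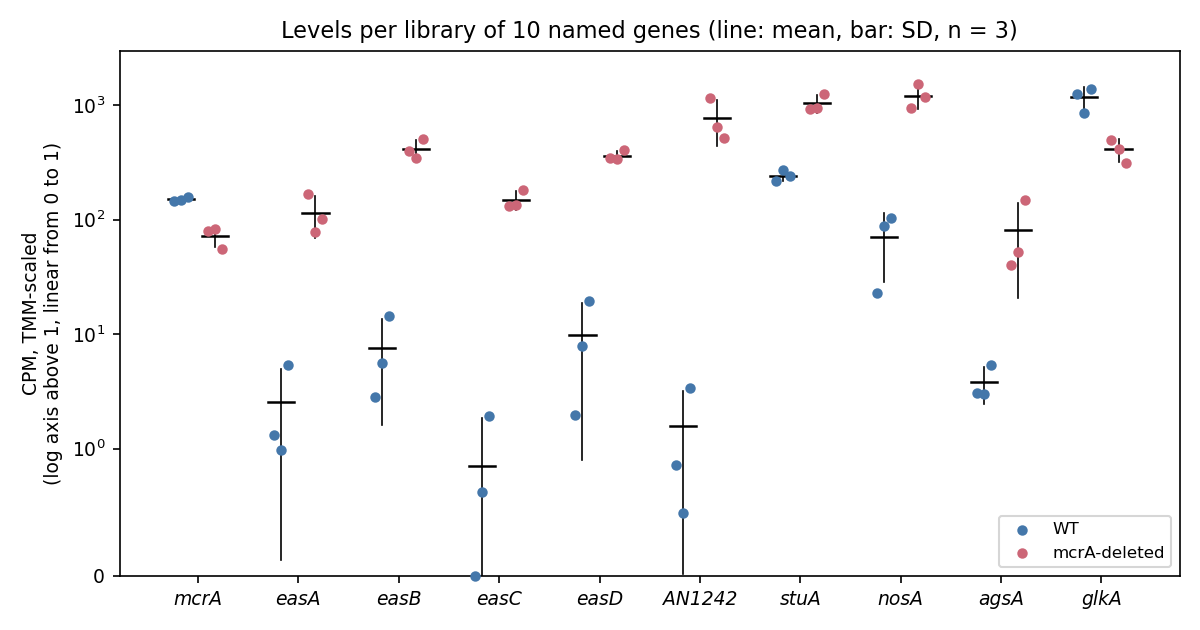
Level in CPM (TMM-scaled; logarithmic axis above 1, linear from 0 to 1) of 10 named genes in each WT and mcrA-deleted library (points), with the mean (line) and SD (bar, n = 3). The 4 emericellamide genes and AN1242 lie at or under 19.4 CPM in every WT library and at or above 77.6 CPM in every mcrA-deleted library, whereas mcrA falls to 48.0% of WT.

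The emericellamide cluster (chromosome VII, 4288441 to 4326107), whose products join a peptide and a polyketide, rose in all 4 of its tested members: easA (AN2545), the peptide synthetase, rose by 5.58 (SE 0.572), easB (AN2547), the polyketide synthase, by 5.80 (SE 0.523), easC (AN2548) by 7.47 (SE 0.508) and easD (AN2549) by 5.24 (SE 0.628) on the log2 scale, with adjusted p from 0.000349 to 0.00203 (edgeR's quasi-likelihood test). In level, easB went from 7.58 ± 5.98 to 416 ± 82.6 CPM and easD from 9.76 ± 8.85 to 363 ± 38.0 CPM. All 4 also passed when adjusted over the list alone, and in each fit that left out 1 library. WT replicate 3 had the highest WT level of each, and without it the log2 values were 6.64, 6.58, 8.55 and 6.13. The list was higher by camera (adjusted p = 0.000762; adjusted p = 0.269 with an estimated correlation).

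Of 26 tested backbone enzymes of secondary metabolism, which make the core structure of a metabolite, 12 rose, 1 fell and 13 did not pass; 15 rose and 1 fell when adjusted over the list alone. Besides AN1242 and easB, the largest rises were in AN10297 (1 count in WT; pooled ratio 228, 40.6 to 9060) and AN2924 (0.718 ± 0.278 to 98.9 ± 59.9 CPM; 7.01, SE 0.637). Without mcrA-deleted replicate 3, AN2924 rose by 6.42 and AN10297 had a ratio of 139 (24.2 to 5540). The 1 WT count of AN10297 lay in replicate 2, without which it was at least 44.2-fold higher. AN5318, named after its value was seen, fell (-1.25, SE 0.367), but its call was lost with library size alone and in 4 of the 6 fits that left out 1 library. Between 9 and 16 members rose when 1 library was left out, with 16 without WT replicate 3. The list was higher by camera (adjusted p = 0.000268; adjusted p = 0.269 with an estimated correlation). Of all 137 members of the 16 listed clusters present in the files, only 43 had enough counts to be tested. Of these 17 rose, 1 fell and 25 did not pass, or 27 rose and 1 fell when adjusted over the list alone. With library size alone, 27 rose over all genes. With a mean count of at least 50, which left 27 cluster genes and 15 backbone enzymes tested, 9 and 6 rose. The filter tests a gene silent in WT only if it has counts in the mcrA-deleted libraries, so the tested members lean towards rises. With no count filter, 23 of 110 cluster genes and 18 of 53 backbone enzymes rose, and 1285 of all 9629 genes tested. With the filter, 1265 of all 7852 tested genes rose. The list of cluster genes was higher by camera, with adjusted p = 5.69e-08 (adjusted p = 0.269 with an estimated correlation).

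The other clusters moved less evenly. Of the 12 tested aspercryptin genes (chromosome II), 5 rose and 7 did not pass, and 10 rose when adjusted over the list alone. AN7877 rose by 3.34 (SE 0.423), from 58.7 ± 27.5 to 598 ± 208 CPM, AN7881 by 4.10 and AN7873 by 4.06; AN7880 went from 2.39 ± 3.14 to 85.6 ± 91.3 CPM, and AN7878, named after its value was seen, rose by 3.22. Levels in the mcrA-deleted libraries were uneven: AN7873 stood at 370.3, 111.5 and 13.9 CPM in replicates 1 to 3, the last under the 16.03 CPM of WT replicate 2. Without mcrA-deleted replicate 1, AN7873, AN7881 and AN7878 stood at 2.67, 3.12 and 2.63, and AN7880 at 3.75 in place of 5.001. Without WT replicate 2, AN7873 and AN7880 stood at 4.68 and 7.13. The number called ranged from 2 (without mcrA-deleted replicate 1 or 2) to 11 (without mcrA-deleted replicate 3); it was 3 without WT replicate 1 or 2, 8 with library size alone and 9 by the DESeq2 Wald test. AN7873 lost its call in 5, and AN7880 and AN7881 in 3 each, of the 6 fits that left out 1 library. The list was higher by camera (adjusted p = 0.00337; adjusted p = 0.468 with an estimated correlation), but not in fry (0.0823), nor by camera (0.0788; 5.52e-06 to 0.0788 over all refits) without WT replicate 3 and mcrA-deleted replicate 1 together.

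In the sterigmatocystin cluster (chromosome IV), 1 of 3 tested genes rose, AN7822 (pooled ratio 71.0, 19.3 to 593). Its WT counts lay in replicate 3, without which it was at least 33.2-fold higher; without WT replicate 2 the ratio was 41.9 (11.4 to 350). All 3 were higher when adjusted over the list alone, and over all genes without WT replicate 3, with library size alone and by the DESeq2 Wald test. Over all genes 2 were higher without mcrA-deleted replicate 1, with the replicate block, with thinned libraries and without mitochondrial features. The remaining 18 members in the files had too few counts, among them the pathway regulator aflR (0 counts over WT, 13 over the mcrA-deleted group) and the synthase stcA (15 and 15). The camera adjusted p was 0.0328 (adjusted p = 0.375 with an estimated correlation). In the orsellinic acid cluster, 1 of 3 tested genes rose, orsC (0 counts in WT; at least 23.7-fold, or 14-fold without WT replicate 2), or 2 adjusted over the list alone; the camera adjusted p was 0.0441 (adjusted p = 0.269 with an estimated correlation), and 0.0526 and 0.0513 without mcrA-deleted replicate 1 or 2, 0.0592 with library size alone, 0.0539 with thinned libraries and 0.0788 without WT replicate 3 and mcrA-deleted replicate 1 together (0.0113 to 0.0788 over all refits). Without WT replicate 3, 3 of the 4 orsellinic acid genes then tested rose, and 2 orsellinic acid genes with library size alone or by the DESeq2 Wald test. Both tested genes of the fellutamide cluster rose, AN3491 (5.13, SE 0.574) and AN3493 (3.14, SE 0.567), both again when adjusted over the list alone. Without WT replicate 2, AN3491 stood at 4.43, and AN3493 kept 2 WT counts, with a pooled ratio of 15.8 (4.15 to 134). Both tested genes of the benzaldehyde derivative (dba) cluster rose, dbaA (3.37, SE 0.66) and AN7895 (2.96, SE 0.765), both again when adjusted over the list alone, although AN7895 lost its call in 4 of the 6 fits that left out 1 library and stood at 2.27 and 3.77 without WT replicates 2 and 3. Of its WT counts dbaA kept 2 without WT replicate 3, with a pooled ratio of 23.2 (6.15 to 196). The polyketide synthase mdpG, the 1 tested monodictyphenone gene, rose by 2.55 (SE 0.469), also when adjusted over the list alone. In the fellutamide, dba and monodictyphenone clusters, 5, 9 and 11 further members in the files had too few counts to be tested. Among these were the backbone enzyme genes inpA and inpB of fellutamide and dbaI of dba, with 5, 10 and 3 counts over the mcrA-deleted group.

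No rise was called among the tested genes of the remaining clusters except for pbcR, the regulator of the ent-pimaradiene cluster (3.38, SE 0.652). It was 1 of 4 tested genes there, called both over all genes and adjusted over the list alone (camera adjusted p = 0.103). With library size alone 2 rose. Without WT replicate 3, 3 of these 4 rose and the camera adjusted p was 0.0143, or 0.0294 without mcrA-deleted replicate 1 as well (0.0143 to 0.243 over all refits); without WT replicate 2 pbcR kept 3 WT counts, with a pooled ratio of 22.6 (7.52 to 111). In the aspernidine cluster 1 of 7 genes fell, AN3231 (-0.63, SE 0.191), which did not pass adjusted over the list alone (0 genes), with library size alone, nor in 4 of the 6 fits that left out 1 library (camera adjusted p = 0.186). With library size alone 2 aspernidine genes rose and 0 fell. Without WT replicate 2, 4 aspernidine genes rose and the camera adjusted p was 0.0333; without mcrA-deleted replicate 2, 2 rose and it was 0.0491 (0.0333 to 0.623 over all refits). The penicillin gene ipnA (1.09, SE 0.606), the asperthecin gene aptC (1.19, SE 0.52), the cichorine gene AN6443 (-0.02, SE 0.314) and the aspyridone genes apdA (1.30, SE 0.456) and AN8415 (0.08, SE 0.346) did not pass; adjusted over the list alone, 1 aspyridone gene, apdA, did, as it did over all genes with library size alone, by the DESeq2 Wald test and without WT replicate 3 (1.96 in the last). Leaving out mcrA-deleted replicate 2 took ipnA to 0.15, and leaving out mcrA-deleted replicate 3 took aptC to 0.40. AN6443 was called lower (-0.58, adjusted p = 0.0257 in the quasi-likelihood test; 0.0257 to 0.988 over all refits) only without WT replicate 3 and mcrA-deleted replicate 1 together. No asperfuranone, terrequinone or austinol gene had enough counts to be tested. In the penicillin, asperthecin, cichorine, aspyridone and ent-pimaradiene clusters, 2, 2, 6, 6 and 4 further members in the files also had too few counts. The lack of calls there covers the tested genes only. With no count filter, 1 of 3 penicillin genes rose.

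**Figure D3:**
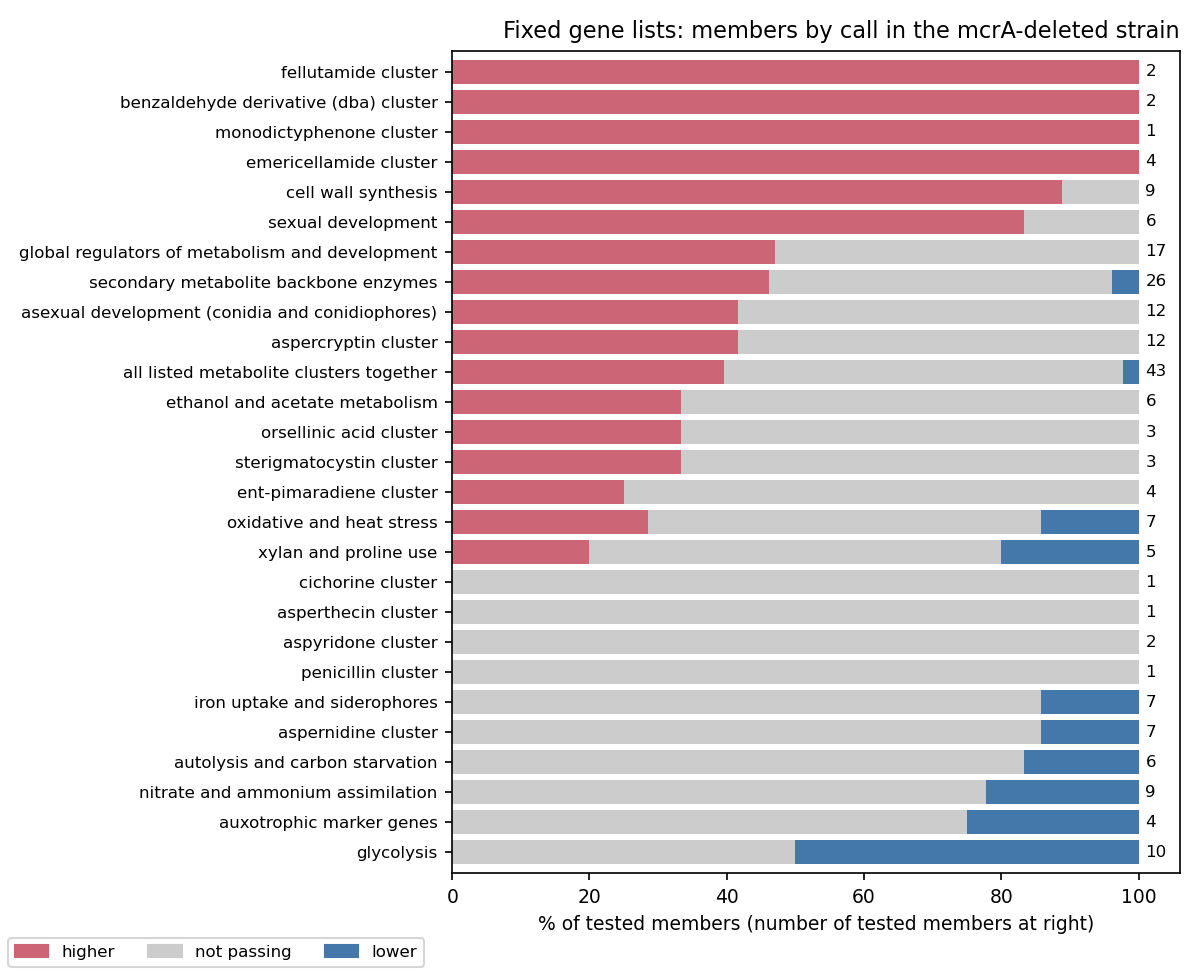
Percentage of the tested members of each fixed gene list with at least 1 tested member that were called higher (red), called lower (blue) or did not pass (grey) in the mcrA-deleted libraries; the number of tested members stands at the right of each bar. All 4 emericellamide genes and 8 of 9 cell wall synthesis genes were called higher, and 5 of 10 glycolysis genes lower.

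Regulators of development and metabolism were higher in part. Of 17 such genes, 8 rose and 9 did not pass, with the same 8 to 0 split adjusted over the list alone. The velvet family genes velC (AN2059) and vosA (AN1959) rose by 3.33 (SE 0.387) and 1.29 (SE 0.146), the developmental regulator stuA (AN5836) by 2.10 (SE 0.193) and laeA (AN0807), a global regulator of metabolite clusters, by 1.16 (SE 0.206) on the log2 scale. The camera adjusted p was 0.00337 (adjusted p = 0.269 with an estimated correlation). The count was 4 without WT replicate 1 or mcrA-deleted replicate 3, and 5 without mcrA-deleted replicate 1 or 2. Without WT replicate 3, velC rose by 3.94.

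Of 6 tested genes of sexual development, 5 rose, also when adjusted over the list alone. Among them stuA, nsdD and veA also stand in the list of regulators above. The transcription factor nosA (AN1848) went from 71.2 ± 42.7 to 1216 ± 293 CPM (4.09, SE 0.553), and stuA, steA (1.17, SE 0.151), nsdD (0.99, SE 0.268) and, named after its value was seen, veA (0.52, SE 0.162) also rose; velB (0.09, SE 0.168) did not pass. The call of veA was lost in all 6 fits that left out 1 library and that of nsdD in 3, and the count was 3 without WT replicate 1 or mcrA-deleted replicate 2 or 3. The camera adjusted p was 0.0037 (adjusted p = 0.269 with an estimated correlation). Of 12 tested genes of asexual development, 5 rose and 7 did not pass, also when adjusted over the list alone. The conidiation regulator brlA (AN0973) rose from 0.344 ± 0.134 to 6.79 ± 4.18 CPM (4.24, SE 0.647), the conidiophore pigment gene ivoB by 4.10 (SE 0.952), vosA as above, the spore pigment synthase wA by 1.27 (SE 0.372) and, named after its value was seen, flbD by 0.89 (SE 0.235). The spore pigment oxidase yA stood at 13.8 ± 3.19 and 9.35 ± 2.98 CPM and did not pass. The calls of wA and flbD were each lost in 4 of the 6 fits that left out 1 library and that of ivoB in 2; the count was 3 without WT replicate 2 or mcrA-deleted replicate 1 or 3, and without the last brlA and ivoB stood at 3.63 and 3.24. The value of ivoB was 4.94 without WT replicate 3. The camera adjusted p was 0.0164 (adjusted p = 0.269 with an estimated correlation), and 0.0656 with a mean count of at least 50 (0.00527 to 0.0656 over all refits).

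Cell wall synthesis genes rose together. Of 9 tested genes 8 rose, also when adjusted over the list alone, and agsB did not pass (0.27, SE 0.167). The alpha-glucan synthase gene agsA (AN5885) went from 3.79 ± 1.34 to 80.9 ± 60.3 CPM (4.44, SE 0.598), and was highest in mcrA-deleted replicate 3 (150.1 CPM), without which it rose by 3.63. The beta-glucan synthase gene fksA rose by 1.04 (SE 0.179) and the chitin synthase genes chsA and chsB by 0.85 (SE 0.122) and 0.75 (SE 0.154). The camera adjusted p was 0.000878 (adjusted p = 0.269 with an estimated correlation). The count was 4 without WT replicate 1 or 2 or mcrA-deleted replicate 2 or 3, and 5 with no count filter.

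Glycolysis genes were the 1 list lower by camera (adjusted p = 0.00175; adjusted p = 0.283 with an estimated correlation). Of 10 genes 5 fell and 5 did not pass, and 7 fell when adjusted over the list alone. The glucokinase gene glkA (AN8689) went from 1171 ± 276 to 412 ± 93.7 CPM (-1.51, SE 0.255), fbaA from 3156 ± 262 to 1631 ± 292 CPM (-0.95, SE 0.21), and AN5746 and pgkA had log2 fold changes of -0.88 (SE 0.208) and -0.80 (SE 0.215); tpiA, named after its value was seen, stood at -0.78 (SE 0.204). The most abundant member, gpdA, stood at 11320 ± 2970 CPM in WT and 6223 ± 1602 CPM in the mcrA-deleted libraries (adjusted p = 0.0726 by edgeR's quasi-likelihood test and 0.00859 by the DESeq2 Wald test; 0.00859 to 0.163 over all refits). The count was 8 without WT replicate 3, 2 without WT replicate 1 or 2, 3 without mcrA-deleted replicate 1 or 3 and 1 without mcrA-deleted replicate 2. The calls of pgkA and tpiA were lost in 5 of these 6 fits, that of AN5746 in 3 and that of fbaA in 1, the fit without mcrA-deleted replicate 2. With library size alone 4 of the 10 fell, and tpiA did not pass. The gene glkA (chromosome III, 3118323 to 3120440) lies close to mcrA (3100552 to 3102696). Of 18 tested genes within 10 genes of mcrA on each side, 4 were lower and 2 higher, against 1078 and 1265 of all 7852. Whether the altered locus itself affects glkA was not tested.

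The other lists of metabolism and stress were not called by camera. In nitrate and ammonium assimilation (9 genes, camera adjusted p = 0.0583), 2 genes fell, the nitrate transporter crnA (-1.61, SE 0.349) and nmrA (-0.90, SE 0.162), and 2 when adjusted over the list alone (4 by the DESeq2 Wald test, 1 without mcrA-deleted replicate 3); the list passed with camera adjusted p = 0.0116 without mcrA-deleted replicate 1, 0.0283 without WT replicate 2, 0.0351 with no count filter, 0.0464 with the replicate block and 0.025 without WT replicate 3 and mcrA-deleted replicate 1 together (0.0116 to 0.125 over all refits). In iron uptake (7 genes, 0.541), the siderophore enzyme gene sidA fell (-1.35, SE 0.216), and 1 gene when adjusted over the list alone; 2 fell without mcrA-deleted replicate 1, with the replicate block and by the DESeq2 Wald test, 2 fell and 1 rose without WT replicate 3, and 1 fell and 1 rose with library size alone. In ethanol and acetate metabolism (6 genes, 0.24), alcA (1.63, SE 0.264) and its activator alcR (1.04, SE 0.317) rose, and 3 genes when adjusted over the list alone; alcR lost its call in 5 of the 6 fits that left out 1 library. By fry the ethanol list was higher, with adjusted p = 0.0068. In oxidative and heat stress (7 genes, 0.78), the catalase genes cpeA (3.49, SE 0.611) and catB (1.89, SE 0.251) rose and AN8269, an hsp90 gene, fell (-1.06, SE 0.295), with the same 2 and 1 adjusted over the list alone, and 2 falls by the DESeq2 Wald test. In xylan and proline use (5 genes, 0.734), prnC rose (2.29, SE 0.356) and prnB fell (-1.97, SE 0.497), 1 each also when adjusted over the list alone. Of 4 auxotrophic marker genes (0.0667), pyroA fell (-0.95, SE 0.181), 1 also when adjusted over the list alone; this list was lower by fry (adjusted p = 0.00736) and by camera with the replicate block (0.0464; 0.0464 to 0.101 over all camera refits). Of 6 autolysis and starvation genes (0.959), acuD fell (-1.68, SE 0.481) and none when adjusted over the list alone (0), and 1 gene rose with library size alone or without mcrA-deleted replicate 1; the median log2 fold change of that list was 0.146 and its mean -0.105, and fry gave the other sign from camera. AN8269, prnB and acuD each lost the call in 4 of the 6 fits that left out 1 library, and crnA in the fit without mcrA-deleted replicate 3; without that library cpeA rose by 2.69.

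Genes that changed in the same direction lay next to each other more often than random placement gives. Of 6567 pairs of adjacent tested genes, 230 were both higher and 170 both lower, together 400, against a mean of 294 and a highest value of 367 in 10000 random placements (permutation p = 1e-04 for each direction, the smallest they can give). The placements counted pairs and not runs, so no expected number of runs is given. Runs of at least 3 adjacent called genes numbered 37 for genes higher (130 genes) and 21 for genes lower (69 genes). The longest, of 10 genes from AN7270 to AN7263, lay on chromosome IV (480279 to 496899): AN7270 rose by 5.19 (SE 0.897; its 7 WT counts were all in WT replicate 3), AN7263 by 4.02 (SE 0.553), and AN12400 between them was the gene at least 54.9-fold higher (26.4-fold without mcrA-deleted replicate 3 and 32.4-fold without WT replicate 2). Runs of 5 genes higher stretched from AN9510 (1.45) over AN2424 (3.25) to AN2426 (0.83) on chromosome VII (3897022 to 3918474) and from AN5492 (1.02) over AN5490 (2.23) to AN5488 (1.97) on chromosome V (2620539 to 2646119). Of the runs of 4 genes higher, the 2 with the largest fitted changes led from AN10731 (0.77) to AN5664 on chromosome V (2038007 to 2043637) and from AN3351 (0 counts in WT; at least 33.9-fold, or 19.99-fold without WT replicate 2) to AN3349 (3.03) on chromosome VI (1000316 to 1013229). Without WT replicate 3, AN7263 and AN3349 rose by 5.08 and 3.89 and AN7270 was at least 66.2-fold higher; without WT replicate 2, AN7270 rose by 4.47. AN9510 lost its call in 4 and AN2426 in 3 of the 6 fits that left out 1 library. Among the runs of 4 genes lower, the most any such run had, that with the largest fall went from AN8134 to AN8137 on chromosome II (859353 to 868113). The count of pairs moved with the number of calls. It was 238, 172 and 523 without WT replicates 1, 2 and 3, and 325, 191 and 212 without mcrA-deleted replicates 1, 2 and 3, each time above the highest of its own 10000 placements (171, 140, 442, 266, 163 and 171).

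**Figure D4:**
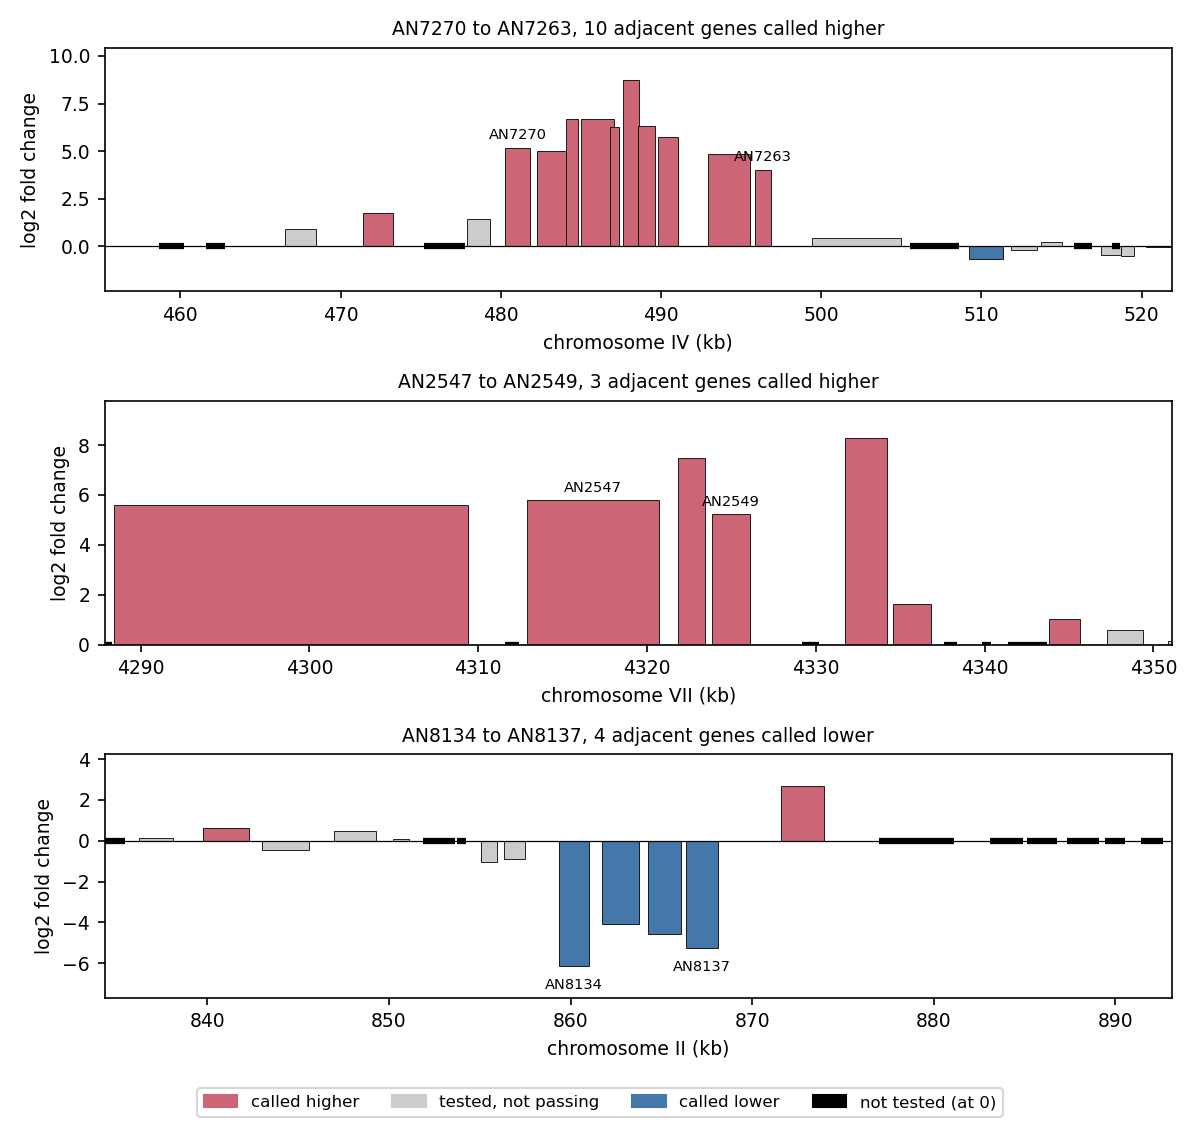
Log2 fold change (mcrA-deleted over WT, fitted) of genes along 3 regions, drawn to scale with chromosome position in kb; red bars were called higher, blue bars called lower, grey bars did not pass and black marks at 0 are genes with too few counts. The 10 genes from AN7270 to AN7263 and the emericellamide genes easB (AN2547) to easD (AN2549) are called higher, and the 4 genes from AN8134 to AN8137 lower; bars of genes with 0 counts in WT, such as AN12400, show fitted values that are not bounds.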

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

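The count filter left 3131 features out of the test. Among these, 42 had 0 counts in all 3 WT libraries and at least 3 counts in each mcrA-deleted library, against 1 feature with the reverse pattern, so there was signal among features that the comparison of genotypes did not use. Of the 42, 4 stand in the lists of metabolite genes: AN8910, AN9314, AN6431 and AN7893, with 53, 45, 34 and 11 counts summed over the mcrA-deleted libraries. The highest of the 42, AN11079 (chromosome V, 487982 to 489082), had 6, 55 and 238 counts in mcrA-deleted replicates 1 to 3, at least 100.4-fold over the WT floor (30.6-fold without mcrA-deleted replicate 3 and 59.2-fold without WT replicate 2). These features were found by their counts and no explanation was tested for them.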

How the results depend on the processing

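In all 15 refits, no gene called in the main comparison and still tested changed sign (0 genes). As 2335 of the 2343 called genes had groups that did not overlap, leaving out libraries could hardly change a sign. That outcome therefore adds little. mcrA stayed lower, with log2 fold changes from -1.16 to -0.90 when 1 library was left out. Fits without 2 libraries, without mitochondrial features and with thinned libraries were chosen after seeing the data. Genes called lower numbered 639 with library size alone. With 1 library left out, 758 to 1496 genes were higher and 618 to 1171 lower, from fewer libraries; 9 to 11 lists were higher and 1 to 2 lower by camera, and 172 to 523 adjacent pairs changed alike. An adjusted p under 0.01 left 575 and 399 genes, and an absolute log2 fold change of at least 1 left 813 and 397, by construction. Leaving out WT replicate 3 and mcrA-deleted replicate 1 together gave 1622 genes higher, 1361 lower, 623 adjacent pairs and 2 lists lower. Lists lower numbered 2 with no count filter, 2 with fry and 3 with the replicate block; the cause was not tested. With an estimated correlation, 0 lists were higher and 0 lower by camera (1 of 20 at an unadjusted p under 0.05; fry called 12). Replicate numbers did not pair the libraries throughout (correlations of same-numbered deviations 0.263, -0.0757 and 0.168). Across genotypes, WT replicates 1 and 3 correlated best with their own number and WT replicate 2 did not, so pairing remains open. The replicate block called 1333 genes higher and 1170 lower. That block ended the call of AN7881 (adjusted p = 0.0752 by edgeR; 0.0151 to 0.0752 over all refits), brought those of the nitrate and marker lists, and changed no other named call.

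Of the named genes, 93 were called; 26 lost the call in at least 1 refit, 17 of these only when 1 library was left out, and 3 others gained one. Only values that did not pass changed sign: AN6443 at 0.14 with library size alone, 0.022 with a mean count of at least 50, 0.16 with thinned libraries and -0.47 to 0.20 with 1 library left out; AN8415 at -0.085 to 0.48 and velB (AN0363) at -0.058 to 0.16 with 1 library left out; and the mean of the autolysis list at 0.061 with library size alone and -0.24 to 0.069 with 1 library left out. The log2 CPM values behind the principal components, camera and fry took a prior count of 2. For genes near 0 counts in WT those values depend on it, and other prior counts were not tried. The DESeq2 Wald test gives no camera value. Of 137 cluster genes in the files, 94 had too few counts to be tested. Simulated 1.5-fold changes were recovered for 5.97% of genes with 200 genes changed, which does not measure recovery in the data, with 2343 calls.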

Other observations

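Tests on mcrA reads, on strongly changed genes split by direction or taken without regard to the call, and on mitochondrial transcripts were chosen after the results were seen, and the test of depth uses a refit added after seeing the data. Some genes outside the fixed lists, named after their values were seen, add to the picture. AN11934, the gene next to AN1242 on chromosome VIII (1095996 to 1101480), went from 1, 1 and 10 counts in WT to 1500, 1476 and 1384 in the mcrA-deleted libraries (log2 fold change 8.60, SE 0.605). Beside the emericellamide genes, AN10325 (chromosome VII, 4331753 to 4334216) had 0 counts in WT and was at least 39.8-fold higher (21.4-fold without mcrA-deleted replicate 3 and 23.5-fold without WT replicate 2). esdC, a gene of early sexual development (AN9121), rose by 2.99 (SE 0.448). The adjacent genes gtb3 and agd3 (AN2955 and AN2954), whose namesakes in A. fumigatus act in making the cell surface polysaccharide galactosaminogalactan, rose by 2.18 (SE 0.418) and 2.31 (SE 0.58); agd3 lost its call in 4 of the 6 fits that left out 1 library. Without WT replicate 3 the values of esdC, gtb3 and agd3 were 3.60, 2.77 and 3.28, and AN11934 kept 2 WT counts, with a pooled ratio of 1720 (475 to 14200); without WT replicate 2, AN11934 rose by 7.99. Lower were sit1 (AN5378), named for a siderophore transporter (-2.06, SE 0.249), and gprC (AN3765), named for a G-protein-coupled receptor (-2.75, SE 0.29). These values are from edgeR's quasi-likelihood fit, with adjusted p from 0.000406 to 0.0229.

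The split of the 6 libraries by genotype gave 2343 called genes, and the highest of the other 9 splits gave 0 (716 genes at an unadjusted p under 0.05 in that with the most, by edgeR). The real split was the 1 split of 10 with as many, and 10 splits are too few for a share under 0.05.

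The feature of the deleted gene kept 48.0% of its WT level. RNA of mcrA+ cells mixed into the mcrA-deleted libraries would leave that share of each gene's WT level, yet 93 genes called lower lay more than 1 log2 unit below mcrA, which argues against such a mixture as the source of the reads. Reads on a part of the feature that the deletion left in place may account for the 48.0%; the tables hold 1 count per feature, so this remains open.

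The axis that parts the genotypes also parts WT replicate 3 from WT replicate 1, and a candidate explanation is that the mcrA-deleted cultures had progressed further. If that were the whole cause, genes should differ between WT replicates 3 and 1 as they differ between genotypes. Strong change here means called genes at least 2 log2 units from WT replicate 2 to the mcrA-deleted mean; the call, though not this difference, used WT replicates 1 and 3. Of 513 such genes 76.8% moved alike, 81.1% of the 417 higher and 58.3% of the 96 lower, where all tested genes gave 58.1%. Taken by the same difference without regard to the call, 82.4% of 459 higher and 58.8% of 97 lower (48.3% to 68.7%, binomial interval) did. Across genes the 2 differences correlated (Pearson r = 0.451 over all tested genes, 0.314 for the 96 lower). WT replicates 1 and 3 also lay apart on the second component (18.95 and -38.04), which does not part the genotypes. Differences beside the genotype axis can lower these shares. They therefore do not decide whether progress was the whole cause, for genes lower or for genes higher. Depth does not account for the calls, as thinning all libraries to the smallest total gave 93.4% as many. Mitochondrial transcripts in mcrA-deleted replicate 1 are not the cause either, since 78.1% of the calls stood in the same direction without that library; leaving out the mitochondrial features alone moves too little to test this. A direct effect of the deletion was not tested apart from these.

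Adjacent genes changed alike beyond random placement also when overlapping features were left out (353 pairs, against a highest of 333 in random placements), which argues against shared reads as the whole cause. Of these pairs 212 were both higher, above the highest placement (194), and 141 both lower, under the highest (148; permutation p = 0.001). A hypothesis was that rises gather near chromosome ends. Of genes called higher, 12.9% lay within 300 kb of an end, against 9.52% of all tested genes; 1000 rotations of the calls along the genome gave a 95th percentile of 11.1% and a highest share of 14.4% (permutation p = 0.01), so position near the ends may go with part of the rises. For genes lower the share was 9.18% (permutation p = 0.7). A further hypothesis was that genes called higher vary more among WT libraries. The median ratio of their difference between WT replicates 1 and 3 to that of uncalled genes of like level was 1.17, with 10 level bins from 0.945 to 1.54, which leaves it open.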
